A study of Homo sapiens with 9 samples.

How the data were processed

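The data were RNA sequencing libraries from THP-1, a human acute monocytic leukemia cell line with a KMT2A fusion. Per the labels' protocols, cells were transduced with lentivirus carrying a control shRNA (shCTRL) or 1 of 2 shRNAs against RASSF2 (shRASSF2-1 and shRASSF2-2). They were then selected in puromycin at 1 ug/mL for 96 h. RNA was taken with TRIzol from 2.0 M viable cells per condition, and libraries were made from poly(A) RNA with random primers. There were 3 libraries in each of 3 groups. The description label names a flow cell for each library: 2 control libraries were on a flow cell of their own, and the other 7 libraries, control replicate 3 among them, shared another. Whether the kit or the counting used strand is not given in the sources used here, so genes that overlap or run antisense to another gene are uncertain, as are near-identical paralogs.

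Per the submitters' processing notes, the authors used HISAT2 2.1.0, Picard, featureCounts 1.6.2 and DESeq2 1.18.1 on genome build hg38. The notes give neither the role nor the order of these tools, and no annotation or filter is given. The deposited table has 18522 genes and a column per library. Per the file headers these columns hold counts, but the deposited values are a normalized signal: in every library 100% of values were whole multiples, within 0.001, of the smallest value above 0. They are therefore gene counts divided by a size factor per library, and the reads could be recovered. The authors also deposited a log2 fold change and an adjusted p-value per gene from a single knockdown against control comparison, and the header does not say which libraries entered it. For 195 genes the table gives an Entrez identifier and no symbol; they carry 0.0694% of reads, stayed in the tests and are not named. For 22 genes the symbol had been turned into a date, and the symbol was taken from the identifier. Positions on GRCh38 were found for 18250 genes by Entrez identifier in RefSeq's gene table.

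The design written before the data were examined named edgeR's quasi-likelihood test on counts, and named limma for normalized values. Because the deposited values were normalized, the main test was limma-trend 3.58.1 in R 4.3.3 on log2(value + 1), with a pseudocount of 1. Fold changes are on that scale. Genes needed a value of at least 10 in at least 3 libraries; 15465 genes were tested and 3057 were left out. All 9 libraries entered a single fit with group as the only term, and genes with a Benjamini-Hochberg adjusted p (FDR) under 0.05 were called. The comparisons were each shRNA against control, the overlap of both, and shRASSF2-2 against shRASSF2-1. The edgeR 4.0.16 test with TMM scaling was run on the recovered reads as an added alternative. Of 15470 genes it called 8741 with shRASSF2-1 and 9386 with shRASSF2-2.

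Before the data were examined, 32 gene lists with 890 genes were fixed, of which 799 entries were tested. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists. Calls were counted over all genes and adjusted over the list alone. Genes named in the text follow a rule fixed at the same time. RASSF2 comes first. Then come the 12 highest and 12 lowest genes called with both shRNAs in the same direction, ranked by the smaller of the 2 fold changes, and the 6 highest and 6 lowest of each other comparison. All of these need a mean of at least 5 CPM. For each list, up to 4 members with a mean of at least 1 CPM and the smallest p over both shRNAs are named. Any other gene is said to be chosen after its values were seen.

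The scripts were tested on simulated data with known changes. For shRASSF2-1 against control, on 15362 genes, limma called 25.8% of genes changed by 1.5-fold, 63.6% of those changed by 2-fold and 95.2% of those changed by 4-fold, with 7 false calls among 125. For shRASSF2-2 against control the shares were 11.8%, 56.2% and 96.8%, with 9 false calls among 61. For shRASSF2-2 against shRASSF2-1, 57.7% of changed genes were called, and for genes changed with both shRNAs 48.5%, with 1 false call each. For shRASSF2-1 against control on 15481 genes, edgeR called 28.8%, 63.6% and 93.7%. The list test, on 15365 genes, called the list that was moved and 0 of the others. Genes were simulated independently, so this does not test for list calls that come from members varying together.

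Alternatives fixed beforehand were DESeq2 1.42.0, size factor scaling in edgeR, a test against a fold of 1.2, no filter, a filter of 1 CPM, pseudocounts of 0.1 and 5, the replicate number as a block, the flow cell as a covariate, the 7 libraries of the shared flow cell alone, fits of the 2 groups compared, and each library left out. The edgeR test with TMM, scaling by total reads, and the list tests on 7 libraries were added after the data were seen. The 7 libraries hold 1 control, so in that fit the spread comes from the knockdown groups alone and any deviation of that control counts as an effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads per library ranged from 13.3 to 20.1 M.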

Results

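Gene expression was measured by poly(A) RNA sequencing in THP-1 cells, a human acute monocytic leukemia line, carrying a control shRNA (shCTRL) or either of 2 shRNAs against RASSF2. The design compared loss of RASSF2, a member of the Ras association domain family that binds the Hippo pathway kinases, by independent shRNAs with the control. Each of the 3 groups had 3 libraries. Reads per library were 13.9, 20.1 and 17.0 M for shCTRL, 13.3, 14.2 and 14.1 M for shRASSF2-1, and 14.5, 14.8 and 15.2 M for shRASSF2-2. Values are the authors' normalized read counts, and group values below are mean ± SD with n = 3. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

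The libraries of each group lay closer to each other than to those of the other groups, and control replicate 1 stood apart from the other controls. The first 3 principal components held 54.0%, 29.2% and 7.41% of the variance, and the third put control replicate 1 at 57.8 and the other controls at -29.4 and -40.7. Across genes, which are not independent replicates, its log2 values correlated with those of the other controls at 0.966 and 0.957, against 0.986 between the latter. Transcripts of the mitochondrial chromosome took 5.86% to 7.45% of reads in the controls, 4.31% to 5.24% with shRASSF2-1 and 2.61% to 3.61% with shRASSF2-2. The mitochondrial ribosomal RNA RNR2 took 2.27% of reads in control replicate 1.

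RASSF2 mRNA was lower in every knockdown library than in every control library. On chromosome 20 (GRCh38, 4780023 to 4823608, Entrez gene 9770), it had normalized read counts of 1104, 1078 and 1010 in the controls, 134, 198 and 159 with shRASSF2-1, and 331, 342 and 262 with shRASSF2-2. The means were 1064 ± 48.4, 164 ± 32.2 and 311 ± 43.5. The log2 fold change was -2.71 with shRASSF2-1 (SE 0.154, limma adjusted p = 3.92e-07) and -1.78 with shRASSF2-2 (SE 0.154, limma adjusted p = 3.08e-06). Residual RASSF2 mRNA was higher with shRASSF2-2 than with shRASSF2-1, by 0.93 (limma adjusted p = 0.00043). In the authors' deposited table RASSF2 had a log2 fold change of -2.07 with an adjusted p-value of 7.95e-10.

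**Figure D1:**
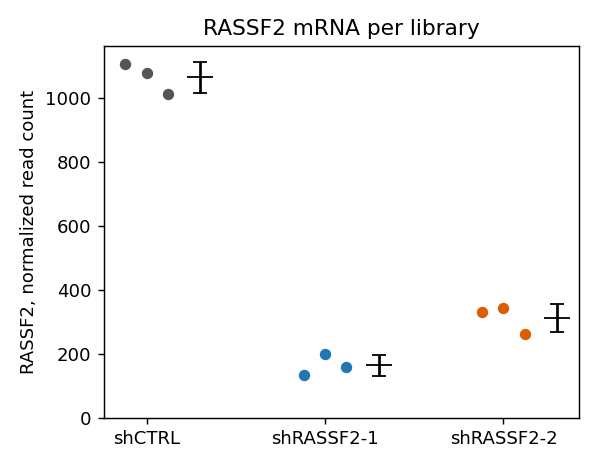
RASSF2 normalized read count (vertical axis, from 0) in each library (points) of the 3 groups (horizontal axis), with the group mean and SD beside the points. The 3 shCTRL libraries lie between 1010 and 1104, the shRASSF2-2 libraries between 262 and 342 and the shRASSF2-1 libraries between 134 and 198.

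The 12 lowest genes called with both shRNAs at a mean of at least 5 CPM included myeloid and cell cycle genes. MS4A3, a membrane protein of granulocyte and monocyte progenitors, had a normalized read count of 1797 ± 184 in the controls, 144 ± 24.3 with shRASSF2-1 and 20.3 ± 5.45 with shRASSF2-2. MYBL2, a transcription factor of cell cycle genes, had log2 fold changes of -3.43 with shRASSF2-1 and -3.83 with shRASSF2-2. CDC20, the mitotic activator of the anaphase-promoting complex, had -3.11 and -3.58, and PCLAF, a PCNA-binding factor, -3.09 and -3.44. Also among the 12 lowest were GAL, the neuropeptide galanin (-4.73 and -3.62), the adhesion protein CEACAM6 (-4.00 and -3.56), the metallothionein MT1G (-3.48 and -3.49), STAR, which carries cholesterol into mitochondria (-3.32 and -3.81), CDCA7 (-3.23 and -3.43), SERPINB10 (-3.21 and -3.61), PPP1R27 (-3.17 and -5.27) and the methionine sulfoxide reductase MSRB3 (-3.20 and -3.05). The largest limma adjusted p of these 12 genes in either comparison was 2.68e-05, for GAL with shRASSF2-2. MT1G belongs to a family of near-identical copies and is uncertain for that reason.

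The 12 highest genes called with both shRNAs at a mean of at least 5 CPM included C1q genes. C1QA, a chain of complement C1q, had a normalized read count of 7.77 ± 7.51 in the controls, 129 ± 5.35 with shRASSF2-1 and 3441 ± 529 with shRASSF2-2. C1QC, another chain, had log2 fold changes of 3.87 and 6.58, and CLEC7A, the beta-glucan receptor dectin-1, 3.69 and 6.85. ZFP36L1, which promotes decay of AU-rich mRNAs, had 4.01 and 6.36. LINC00599 (3.92 and 4.18), the acetyltransferase gene NAT2 (6.04 and 3.62), IGFBP3, a binding protein of insulin-like growth factors (3.44 and 3.64), and the homeobox gene MEIS3 (3.43 and 3.58) also rose. Within the 7 libraries of the shared flow cell, the values with shRASSF2-1 were 3.02 for C1QA and 2.29 for C1QC, and NAT2 had 2.39 with shRASSF2-2. All of these were called by limma with both shRNAs. C1QC had normalized read counts of 3.63, 2.49 and 19.7 in the controls and 30.5, 222 and 148 with shRASSF2-1. Like SPARC and FCGBP below, it was higher in control replicate 3 than in the 2 controls of the separate flow cell.

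The other 4 of the 12 highest genes were SPARC, STAB1, FCGBP and KRT18. SPARC and STAB1 were taken as markers of connective tissue and vessel, and FCGBP and KRT18 of gut epithelium. Whether THP-1 cells themselves express these 4 genes was not tested. They were near 0 in the 2 control libraries of the separate flow cell and present in control replicate 3 as well as in all knockdown libraries. FCGBP had normalized read counts of 3.63, 2.49 and 331 in the controls, 119, 1228 and 1064 with shRASSF2-1, and 955, 935 and 1545 with shRASSF2-2. SPARC had 0, 2.49 and 69.4 in the controls. Over all libraries the log2 fold changes with shRASSF2-1 and shRASSF2-2 were 5.04 and 5.34 for SPARC, 4.95 and 5.99 for FCGBP, 4.70 and 4.38 for STAB1, and 4.12 and 4.85 for KRT18. With edgeR on the recovered reads they were 3.43 and 3.55 for SPARC, 2.82 (edgeR adjusted p = 0.0544) and 3.30 for FCGBP, 3.97 and 3.51 for STAB1, and 1.59 (0.254) and 1.86 (0.180) for KRT18. DESeq2 called STAB1 with both shRNAs and SPARC with shRASSF2-2, and not SPARC with shRASSF2-1 (DESeq2 adjusted p = 0.0519), FCGBP (0.126 and 0.0623) or KRT18 (0.487 and 0.393). In the 7 libraries of the shared flow cell they were 1.55 and 1.85 for SPARC, 0.70 and 1.75 for FCGBP, 2.49 and 2.17 for STAB1, and -0.45 and 0.28 for KRT18; of these values limma called those of STAB1. With flow cell as a covariate in all 9 libraries the call of STAB1 with shRASSF2-2 was lost (limma adjusted p = 0.0644). Leaving out control replicate 2, shRASSF2-1 replicate 2 or shRASSF2-1 replicate 3 ended the call of FCGBP with shRASSF2-1, with limma adjusted p of 0.0684, 0.0628 and 0.0622. For KRT18 with shRASSF2-2 the call was lost without control replicate 2 (0.0755), shRASSF2-2 replicate 1 (0.0567) or shRASSF2-2 replicate 2 (0.0553). With shRASSF2-1 it was lost without control replicate 1 (0.0627), control replicate 2 (0.146), shRASSF2-1 replicate 1 (0.0897), shRASSF2-1 replicate 2 (0.142), or shRASSF2-2 replicate 1, 2 or 3 (0.0607, 0.0622 and 0.0603), and without control replicate 3 the log2 fold change was 6.41.

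The epithelial marker list had fewer genes up within the shared flow cell. With shRASSF2-1, 3 of its 8 members rose, 1 fell and 4 were not called (median 1.44, camera FDR 0.411; 4 up and 1 down adjusted over the list alone). With shRASSF2-2, 7 rose and 1, CDH2, fell (median 2.77, camera FDR 0.230; the same counts adjusted over the list alone). In the 7 libraries of the shared flow cell, 1 rose and 1 fell with shRASSF2-1, and 3 rose and 1 fell with shRASSF2-2. Without control replicate 1, 1 rose and 1 fell with shRASSF2-1, and 7 rose and 1 fell with shRASSF2-2. VIM, the intermediate filament protein of mesenchymal and myeloid cells, rose by 1.22 and 0.58.

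**Figure D2:**
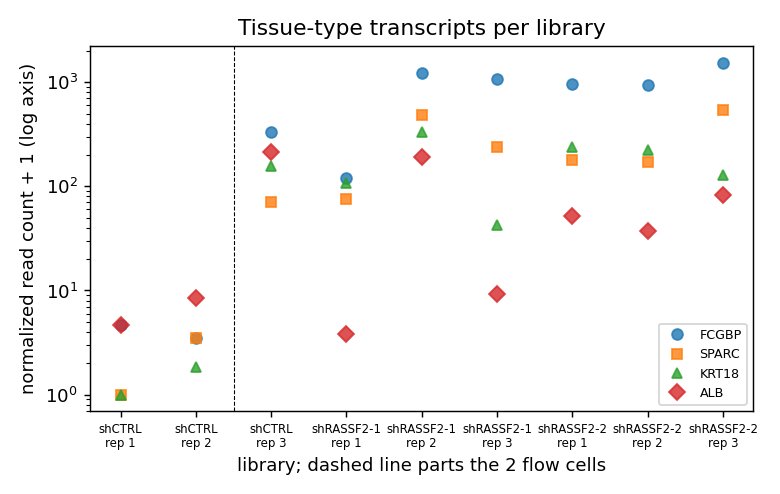
Normalized read count plus 1 (vertical log axis) of FCGBP, SPARC, KRT18 and ALB in each of the 9 libraries (horizontal axis, 1 point per gene and library), with a dashed line between the 2 flow cells. FCGBP is at 3.63 and 2.49 in the controls left of the line, 331 in the control right of it, and 119 to 1545 in the knockdown libraries.

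Cell division genes fell with both shRNAs. All 41 members of the DNA replication and G1/S list fell with each shRNA, with median log2 fold changes of -1.68 with shRASSF2-1 (camera FDR 1.86e-17) and -2.28 with shRASSF2-2 (camera FDR 1.46e-20). With an estimated correlation the adjusted p was 0.139 and 0.0726. Of 39 members of the mitosis and G2/M list, 38 fell with shRASSF2-1 (median -1.77, camera FDR 2.06e-15), 1 was not called, and all 39 fell with shRASSF2-2 (median -3.29, camera FDR 7.43e-21), with adjusted p = 0.243 and 0.141 with an estimated correlation. The replicative helicase subunits MCM2 (-2.68 and -2.59) and MCM7 (-1.85 and -2.84), the maintenance methylation factor UHRF1 (-2.16 and -3.26), and the ribonucleotide reductase subunit RRM1 (-2.53 and -1.96) fell, as did the mitotic kinase PLK1 (-1.99 and -3.30), the topoisomerase TOP2A (-2.83 and -3.39) and the spindle motor KIF11 (-2.17 and -3.10). Adjusted over the list alone, the counts of both lists were equal to these. Without control replicate 1, and in the 7 libraries of the shared flow cell, the same numbers fell.

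Genes of ribosome production and mitochondrial respiration also fell with both shRNAs. Of 36 genes of ribosome biogenesis and MYC targets, 33 fell, 1 rose and 2 were not called with shRASSF2-1 (median -0.99, camera FDR 2.50e-11), and 35 fell and 1 was not called with shRASSF2-2 (median -1.22, camera FDR 2.89e-12), with adjusted p = 0.0629 and 0.0508 with an estimated correlation. Among them were the lactate dehydrogenase subunit LDHA (-1.63 and -2.12), the growth regulator PA2G4 (-1.50 and -1.55), the ribosomal RNA processing factor UTP20 (-1.85 and -1.58) and spermidine synthase SRM (-1.79 and -1.77). Of 48 cytosolic ribosomal protein genes, 47 fell and 1 was not called with each shRNA (medians -1.02 and -1.33, camera FDR 2.45e-17 and 1.21e-18), with adjusted p = 0.155 and 0.108 with an estimated correlation. RPSA had -1.86 and -2.01, RPLP0 -1.77 and -2.16, RPS3 -1.44 and -1.51, and RPS6 -1.14 and -1.53. Nuclear genes of oxidative phosphorylation fell in 27 of 34 members with shRASSF2-1 and 7 were not called (median -0.68, camera FDR 4.70e-08); with shRASSF2-2, 25 fell, 1 rose and 8 were not called (median -0.65, camera FDR 1.68e-05). With an estimated correlation the adjusted p was 0.243 and 0.253. COX5A of complex IV had -1.60 and -0.74, and ATP5PO of ATP synthase -1.18 and -0.87. Of 13 mitochondrially encoded mRNAs, 9 fell with shRASSF2-1 (median -0.82, camera FDR 0.0173) and 11 with shRASSF2-2 (median -1.48, camera FDR 0.000352), and the others were not called; adjusted p = 0.531 and 0.276 with an estimated correlation. COX3 had -1.32 and -1.88, and ND4L -1.09 and -1.96. Without control replicate 2 the camera FDR of this list with shRASSF2-1 was 0.05004 and its call was lost. With scaling by total reads the shRASSF2-1 values shrank: ribosome biogenesis had 27 down and 1 up (median -0.61), ribosomal proteins 44 down (-0.64), nuclear oxidative phosphorylation genes 19 down and 1 up (-0.30) and mitochondrially encoded mRNAs 6 down (-0.44). Adjusted over the list alone, 10 of the mitochondrially encoded mRNAs fell with shRASSF2-1, and all other counts in these 4 lists were equal. Without control replicate 1, which had the highest share of RNR2, all 13 mRNAs fell with each shRNA. In the 7 libraries of the shared flow cell 10 fell with shRASSF2-1 and 13 with shRASSF2-2, and with flow cell as a covariate 2 and 10.

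Inflammatory genes and some histone genes rose with both shRNAs. In the NF-kB and inflammatory cytokine list of 31 genes, 20 rose, 5 fell and 6 were not called with shRASSF2-1 (median 1.11, camera FDR 0.000247), and 26 rose and 5 were not called with shRASSF2-2 (median 1.54, camera FDR 3.27e-07); adjusted p = 0.448 and 0.221 with an estimated correlation. The adhesion receptor ICAM1 rose by 2.20 and 3.59, the ubiquitin ligase BIRC3 by 3.17 and 2.05, the adaptor TRAF1 by 2.27 and 2.09, and TNFAIP2 by 1.11 and 1.79. Of 14 replication-dependent histone genes, 5 rose, 1 fell and 8 were not called with shRASSF2-1 (median 1.38, camera FDR 0.0222), and 8 rose, 1 fell and 5 were not called with shRASSF2-2 (median 2.38, camera FDR 0.0305), with adjusted p = 0.155 and 0.141 with an estimated correlation. HIST2H2BE rose by 2.16 and 4.91, HIST1H2BK by 1.72 and 2.64 and HIST1H2BC by 1.44 and 2.37, while HIST2H2AC had -2.94 and -1.81. These histone genes have near-identical copies and are uncertain. The libraries were made from poly(A) RNA, so the values cover only polyadenylated histone transcripts and need not follow total histone mRNA. With scaling by total reads the histone list lost its call with shRASSF2-1 (camera FDR 0.181), and without control replicate 1, 11 of its members rose with shRASSF2-1. Adjusted over the list alone, the counts of both lists were equal.

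In all, 4834 of 15465 genes tested (31.3%) were called by limma with both shRNAs in the same direction, 2248 up and 2586 down. Of these, 1660 changed at least 2-fold with both, 808 up and 852 down. Independent call lists of the same sizes would share 1322 genes up and 1313 down. Both comparisons use the same controls. In 20 simulated sets, all 9 libraries, controls included, were drawn independently around a common mean per gene. There 0.05 genes on average (0 to 1) were called in the same direction. The draws hold neither the deviation of control replicate 1 across genes nor a flow cell difference. They cannot say how many shared calls the real controls could give. The covariance of the fold changes across genes was 0.593, against 0.0428 simulated, a difference of 0.550, and r was 0.449 against 0.501 simulated; 67.4% of genes had the same sign, against 66.6%. With 3 controls, no split leaves 2 of them on each side, so part of the excess may come from the shared controls. In the 7 libraries of the shared flow cell, with a single control, 5030 genes were called in the same direction, and with flow cell as a covariate 3453. With scaling by total reads the split was 3097 up and 1671 down. Of 5885 genes with an adjusted p-value under 0.05 in the authors' deposited table, 4736 were among the 4834.

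Among called genes with a mean of at least 5 CPM, the 6 that fell most with shRASSF2-1 against control were GAL, MT1E, HSD11B1, OAS2, ISG15 and PAX5. MT1E fell from 2065 ± 817 to 91.6 ± 10.3 (log2 fold change -4.40), and HSD11B1, which regenerates cortisol, from 354 ± 108 to 17.3 ± 3.94 (-4.24). OAS2, a sensor of double-stranded RNA, fell from 9770 ± 1433 to 528 ± 45.3 (-4.20), and ISG15, a ubiquitin-like protein, from 3332 ± 642 to 188 ± 18.9 (-4.13). PAX5, a B cell transcription factor, had -4.09. The highest besides NAT2, SPARC, FCGBP and STAB1 were AKR1C2, a ketosteroid reductase, which rose from 109 ± 26.9 to 4191 ± 142 (5.28), and the chemokine CXCL1, which rose from 16.1 ± 13.7 to 389 ± 79.0 (5.14). The largest limma adjusted p of the genes given here with values was 0.000215, for CXCL1. MT1E and AKR1C2 have near-identical copies and are uncertain.

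Stress response genes were lower with shRASSF2-1, and heat shock genes to a lesser degree with shRASSF2-2 as well. Of 17 heat shock genes, 15 fell and 2 were not called (median -1.14, camera FDR 5.34e-06, 16 down adjusted over the list alone), with adjusted p = 0.399 with an estimated correlation. With shRASSF2-2, 8 fell, 2 rose and 7 were not called (median -0.47, camera FDR 0.0413, 9 down and 2 up adjusted over the list alone; 13 down and 2 up without control replicate 1 and in the 7 libraries of the shared flow cell), with adjusted p = 0.630 with an estimated correlation. The chaperones HSP90AA1 (-1.67 and -1.58), HSPD1 (-1.66 and -1.46) and HSP90AB1 (-1.47 and -1.09) fell with both. The list lost its call with shRASSF2-2 without control replicate 2 (camera FDR 0.0685), control replicate 3 (0.0703), shRASSF2-2 replicate 1 (0.0509) or shRASSF2-2 replicate 3 (0.0530). In shRASSF2-2 against shRASSF2-1, 9 heat shock genes were higher and 8 were not called (median 0.49, camera FDR 0.00912). That call was lost with an estimated correlation (camera adjusted p = 0.512). In the unfolded protein response list of 24 genes, 15 fell, 2 rose and 7 were not called with shRASSF2-1 (median -0.57, camera FDR 0.00310), with adjusted p = 0.155 with an estimated correlation. Without control replicate 1, 17 fell and 4 rose with shRASSF2-1. With shRASSF2-2, 9 rose and 8 fell (median -0.04, camera FDR 0.675, 9 and 9 adjusted over the list alone, 9 and 10 without control replicate 1). The transcription factor XBP1 had -1.67 and -1.52, and the chaperones HYOU1 -1.31 and -0.88, HSP90B1 -1.19 and -0.86 and CRELD2 -1.19 and -1.68. Of 32 ATF4 and amino acid response genes, 18 fell, 3 rose and 11 were not called with shRASSF2-1 (median -0.52, camera FDR 0.0173), with adjusted p = 0.466 with an estimated correlation and camera FDR 0.0526 without control replicate 3. With shRASSF2-2, 12 rose and 11 fell (median 0.24, mean 0.14, camera test up with FDR 0.980, 13 and 11 adjusted over the list alone), and the test turned down without control replicate 1 (0.907) or shRASSF2-2 replicate 2 (0.952), with flow cell as a covariate (0.731) and in the 7 libraries of the shared flow cell (0.850). PHGDH, the first enzyme of serine synthesis, had -2.50 and -2.82, VLDLR -1.49 and -2.67, SHMT2 -1.08 and -1.12, and the tryptophanyl-tRNA synthetase WARS -0.83 and 0.68. Scaling by total reads left the unfolded protein response list at 11 down and 7 up (median -0.19) and the ATF4 list at 13 down and 8 up (median -0.14) with shRASSF2-1, and the heat shock list at 11 down (median -0.77). Adjusted over the list alone, the shRASSF2-1 counts of the last 2 lists were equal.

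For the remaining metabolic lists the direction with shRASSF2-1 depended on the scaling. The cholesterol biosynthesis list of 26 genes had 13 down and 2 up with shRASSF2-1 (median -0.34, or 0.03 with scaling by total reads; camera FDR 0.0824) and 8 up and 8 down with shRASSF2-2 (median -0.12, camera FDR 0.913). The farnesyl diphosphate synthase FDPS (-1.31 and -1.35) and the desaturase SCD (-2.13 and -0.99) fell with both, and CYP51A1 had -0.80 and 0.49. Without control replicate 1 or shRASSF2-1 replicate 2 the list was called with shRASSF2-1 (camera FDR 0.0133 and 0.0489), and in the 7 libraries of the shared flow cell as well (0.0302). The hypoxia and glycolysis list of 32 genes had 14 down and 7 up with shRASSF2-1 (16 and 7 adjusted over the list alone; median -0.27, or 0.11 with scaling by total reads; camera FDR 0.146). With shRASSF2-2 it had 13 down and 10 up (median -0.03, mean 0.08, camera test down with FDR 0.552). The glucose transporter SLC2A1 (-1.10 and -1.43) and the enolase ENO1 (-1.23 and -0.85) fell, and the collagen prolyl hydroxylase P4HA2 rose by 1.59 and 1.51. The counts not given separately were equal when adjusted over the list alone.

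With shRASSF2-1, limma called 8669 genes (56.1%), 4160 up and 4509 down, 3681 of them by at least 2-fold. The normalized total was 12.6 to 12.8 M per library with shRASSF2-1 and 15.9 to 16.9 M in the other groups. Scaling by total reads moved the median of all genes with shRASSF2-1 from 0.02 to 0.39 and the split to 6981 up and 2596 down, so the share called up went from 48.0% to 72.9%. The median log2 fold change also fell with expression, from 0.50 in genes with a mean log2 value under 5 to -0.31 in those over 11. In the 7 libraries of the shared flow cell 8887 genes were called, and with flow cell as a covariate 6420.

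Among called genes with a mean of at least 5 CPM, the 6 that rose most with shRASSF2-2 against control were C1QA, ADAMDEC1, GBP1, RGS1, ZBP1 and RASGEF1B. ADAMDEC1, a metalloprotease gene of macrophages, rose from 20.5 ± 9.48 to 11670 ± 960 (log2 fold change 9.20). GBP1, an interferon-induced GTPase, rose from 24.2 ± 3.07 to 6280 ± 532 (7.96), RGS1, a regulator of G protein signalling, from 4.54 ± 2.62 to 1279 ± 81.1 (7.95), and RASGEF1B from 4.40 ± 3.81 to 661 ± 68.6 (7.41). ZBP1, a sensor of Z-form nucleic acid, rose from 4.30 ± 6.07 to 693 ± 114. The lowest besides MS4A3 and PPP1R27 were SERPINB2, the plasminogen activator inhibitor 2, which fell from 1256 ± 674 to 10.4 ± 7.38 (-6.79), WNT7B (-5.37), LINC01140 (-4.66) and the transglutaminase TGM5 (-4.58). The largest limma adjusted p of the genes given here with values was 1.15e-05, for RASGEF1B.

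Monocyte and macrophage genes rose with shRASSF2-2. Of 34 list members, 22 rose, 8 fell and 4 were not called (median 1.85, camera FDR 0.00123, 23 up and 8 down adjusted over the list alone), with adjusted p = 0.141 with an estimated correlation. With shRASSF2-1, 13 rose, 10 fell and 11 were not called (median 0.28, camera FDR 0.431, 14 up and 10 down adjusted over the list alone). The scavenger receptor CD36 rose by 2.12 with shRASSF2-1 and 3.26 with shRASSF2-2, and the integrin ITGAM by 1.66 and 1.56, while IRF8, a transcription factor of monocyte progenitors, had -2.16 and -2.73. In the MHC class II list of 8 genes, 6 rose and 2 were not called with shRASSF2-2 (median 1.57, camera FDR 0.00360), with adjusted p = 0.253 with an estimated correlation; with shRASSF2-1, 2 rose, 1 fell and 5 were not called (median 0.26, camera FDR 0.433). The lysosomal thiol reductase IFI30 rose by 2.07 and 6.86. HLA-DRB1 rose by 0.95 and 2.00, with 0.54 for shRASSF2-1 without control replicate 1 and 0.62, not called (limma adjusted p = 0.207), with flow cell as a covariate, and CIITA, the class II transactivator, had 0.23, not called, and 1.04. In the MHC class I list of 11 genes, 7 rose and 4 were not called with shRASSF2-2 (median 0.89, camera FDR 0.0305, 7 up and 1 down adjusted over the list alone), with adjusted p = 0.169 with an estimated correlation. With shRASSF2-1, 6 fell, 2 rose and 3 were not called (median -0.64, camera FDR 0.240, 3 up and 6 down adjusted over the list alone), or 2 fell and 3 rose with scaling by total reads (median -0.26). The class I light chain B2M had -0.94 (-1.43 in the 7 libraries of the shared flow cell, and -0.56, limma adjusted p = 0.0978, with scaling by total reads) and 2.30, the chaperone CALR -1.44 and 0.59, and the class I transactivator NLRC5 -0.64 and 0.89, where -0.64 lost its call with flow cell as a covariate (0.0641) and with scaling by total reads (0.112). HLA genes have near-identical copies and are uncertain. The immediate early and MAPK feedback list of 32 genes had 21 up and 7 down with shRASSF2-2 (median 1.25, camera FDR 0.00128) and 10 up and 4 down with shRASSF2-1 (median 0.16, camera FDR 0.240), with adjusted p = 0.159 for shRASSF2-2 with an estimated correlation. The ERK phosphatase DUSP6 rose by 2.31 and 3.36, PHLDA1 by 1.12 and 2.62, KLF6 by 0.69 and 2.34 and JUN by 0.80 and 1.98. Counts not given separately were equal when adjusted over the list alone.

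Adhesion, YAP target and actin genes also rose with shRASSF2-2. In the integrin and migration list of 33 genes, 23 rose, 7 fell and 3 were not called (median 1.29, camera FDR 0.00110), with adjusted p = 0.0726 with an estimated correlation. With shRASSF2-1, 11 rose and 9 fell (median 0.00, or -0.03 with TMM scaling and 0.38 with scaling by total reads; camera FDR 0.782; 11 and 10 adjusted over the list alone). ITGB7 had -1.19 with shRASSF2-1 and 3.46 with shRASSF2-2, ITGA4 -1.28 and 1.14, and the gelatinase MMP9 3.73 and 2.58. Of 22 YAP/TAZ target genes, 12 rose, 2 fell and 8 were not called with shRASSF2-2 (median 1.15, camera FDR 0.0184, 13 up and 2 down adjusted over the list alone), with adjusted p = 0.276 with an estimated correlation. With shRASSF2-1, 9 rose and 4 fell (median 0.67, camera FDR 0.224). IGFBP3 rose with both, MYOF had -0.88 and 1.86, and ASAP1 -0.36, or 0.02 with scaling by total reads, and 1.58. The actin nucleation list of 27 genes had 16 up, 2 down and 9 not called with shRASSF2-2 (median 0.35, camera FDR 0.00311; 19 up and 4 down without control replicate 1), with adjusted p = 0.108 with an estimated correlation. With shRASSF2-1 it had 13 down and 7 up, or 7 down and 13 up with scaling by total reads (median -0.18, or 0.20 with that scaling; camera FDR 0.424). The Arp2/3 subunit ARPC5 had -0.91 and 0.75, EVL -0.79 and 1.09, VASP 0.57 and 1.05 and WASL 1.48 and 1.12. The counts not given separately were equal when adjusted over the list alone.

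The Rac GTPase signaling list had medians of opposite sign with the 2 shRNAs, but its calls against control were easily lost. Among its members, 7 were called in opposite directions, 4 up with both and 7 down with both. Of 34 genes, 17 fell, 4 rose and 13 were not called with shRASSF2-1 (median -0.41, camera FDR 0.0326), and 18 rose, 8 fell and 8 were not called with shRASSF2-2 (median 0.36, camera FDR 0.0442), with the same counts adjusted over the list alone. With an estimated correlation the adjusted p was 0.155 and 0.141. The NADPH oxidase subunits CYBB (1.72 and 3.42) and NCF1 (0.83 and 1.57) rose with both, and the exchange factor ARHGEF6 (-1.04 and -1.35) and RACGAP1 (-1.25 and -1.86) fell with both; NCF1 has near-identical pseudogenes and is uncertain. The call with shRASSF2-1 ended without control replicate 1 (camera FDR 0.0645), in the 7 libraries of the shared flow cell (0.0885), with flow cell as a covariate (0.0883) and with scaling by total reads (0.120), where 13 rose and 11 fell. That with shRASSF2-2 ended without control replicate 2 (0.0501) or control replicate 3 (0.0705).

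The lists closest to RASSF2 itself were not called against control. The RASSF family list holds RASSF2, so the targeted gene is among the members counted as fallen with each shRNA. In the RASSF family list of 8 genes, 4 fell and 1 rose with shRASSF2-1 (median -0.29, or 0.09 with scaling by total reads; camera FDR 0.411), and 2 rose and 2 fell with shRASSF2-2 (median 0.02, or -0.03 with TMM scaling, mean -0.09, camera test up with FDR 0.913). RASSF4 rose by 0.50 and 0.67, and RASSF3 had -0.44 and 1.42; its call with shRASSF2-1 was lost in the 7 libraries of the shared flow cell (-0.28, limma adjusted p = 0.0731), with flow cell as a covariate (0.162), in the edgeR test against a fold of 1.2 (0.0609) and with scaling by total reads (-0.06, 0.645). Without control replicate 1, and in the 7 libraries, 4 of the 8 RASSF genes rose and 3 fell with shRASSF2-2. In the Hippo pathway core list of 27 genes, 8 fell and 6 rose with shRASSF2-1 (median 0.02, or -0.02 with TMM scaling and 0.38 with 6 down and 12 up with scaling by total reads, mean -0.02, camera test up with FDR 0.931), and 8 rose and 7 fell with shRASSF2-2 (median 0.13, mean -0.14, camera test up with FDR 0.934). The kinases TAOK3 (0.71 and 1.24) and LATS2 (0.59 and 1.58) rose, as did WWC2 (1.16 and 0.64), and the angiomotin family gene AMOTL1 had -1.54 and -2.81. The Hippo list had 9 up and 9 down with shRASSF2-1, and 11 up and 8 down with shRASSF2-2, without control replicate 1. The test of the Hippo list turned down without control replicate 3 with shRASSF2-1 (0.850), and without control replicate 2 (0.976) or control replicate 3 (0.839) with shRASSF2-2. The counts of both lists were equal when adjusted over the list alone.

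The leukemia, survival and lineage lists were not called either. Of 31 KMT2A fusion targets and leukemia stem genes, 11 fell and 8 rose with shRASSF2-1 (median -0.07, or 0.31 with 4 down and 13 up with scaling by total reads; camera FDR 0.765), and 11 rose and 10 fell with shRASSF2-2 (median -0.22, camera FDR 0.504, 11 and 11 adjusted over the list alone). The apoptosis inhibitor BCL2 had -2.73 and -2.04, the receptor kinase FLT3 -3.24 and -1.80, and CPEB2 1.35 and 0.77. Of 28 p53 target genes, 12 rose and 9 fell with shRASSF2-1 (median -0.00, or 0.38 with scaling by total reads; camera test up with FDR 0.782; 12 and 10 adjusted over the list alone), and 13 rose and 5 fell with shRASSF2-2 (median 0.41, camera FDR 0.128, 14 and 5 adjusted over the list alone, 14 and 9 without control replicate 1, and 12 and 9 in the 7 libraries of the shared flow cell). BTG2 rose by 1.80 and 3.40, TP53INP1 by 2.45 and 2.56, and CDKN1A, the cyclin-dependent kinase inhibitor p21, had -1.39 and 2.93. Of 39 apoptosis regulators, 12 fell and 11 rose with shRASSF2-1 (median 0.02, or 0.40 with 5 down and 20 up with scaling by total reads; camera FDR 0.726), and 19 rose and 10 fell with shRASSF2-2 (median 0.31, camera FDR 0.0716, or 0.0487 without control replicate 3; 21 and 10 adjusted over the list alone). BMF, a BH3-only protein, rose by 2.01 and 4.32, and CFLAR by 0.89 and 1.37. Of 13 neutrophil granule genes, 6 fell and 1 rose with shRASSF2-1 (median 0.08, or -0.15 with TMM scaling, mean -0.44, camera test down with FDR 0.420), and 8 fell and 3 rose with shRASSF2-2 (median -1.76, camera FDR 0.0598, called without shRASSF2-1 replicate 1, shRASSF2-2 replicate 2 or shRASSF2-2 replicate 3 at 0.0460, 0.0404 and 0.0470, and in the 7 libraries of the shared flow cell at 0.0365). Myeloperoxidase MPO had -4.42 and -3.48, and serglycin SRGN -1.01 and -1.76. Few markers of other blood lineages passed the filter. In the erythroid list of 2 tested genes, the transferrin receptor TFRC fell with both (-1.28 and -0.81) and KLF1 was not called (medians -1.22 and 0.54, camera test down with FDR 0.249 and 0.627). Without control replicate 1, and with flow cell as a covariate, 1 erythroid gene rose and 1 fell with shRASSF2-2. In the T and NK cell list of 5 genes, 2 rose and 2 fell with shRASSF2-1 (median 0.40, camera FDR 0.909), and 3 rose and 1 fell with shRASSF2-2 (median 0.87, camera FDR 0.564). In the B cell list of 5 genes, 1 rose and 1 fell with shRASSF2-1 (median 0.24, mean -0.58, camera test down with FDR 0.914), and 3 rose and 1 fell with shRASSF2-2 (median 1.09, camera FDR 0.422). Counts not given separately were equal when adjusted over the list alone.

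With shRASSF2-2, limma called 9417 genes (60.9%), 4913 up and 4504 down, 4765 of them by at least 2-fold. In the 7 libraries of the shared flow cell 9509 were called, and with flow cell as a covariate 7484.

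The 2 shRNAs differed most in interferon response genes, which fell with shRASSF2-1 and rose with shRASSF2-2. Of 45 members, 40 fell, 2 rose and 3 were not called with shRASSF2-1 (median -2.14, camera FDR 4.49e-18), and all 45 rose with shRASSF2-2 (median 1.88, camera FDR 1.81e-19), with the same counts adjusted over the list alone. With an estimated correlation the adjusted p was 0.123 and 0.0726. IFIT1, which binds foreign RNA, had 2931 ± 562 in the controls, 176 ± 13.5 with shRASSF2-1 and 30263 ± 2646 with shRASSF2-2. IFIT3 had log2 fold changes of -3.14 and 3.28, EPSTI1 -2.55 and 2.76 and the antiviral GTPase MX2 -2.45 and 1.70. In the test of shRASSF2-2 against shRASSF2-1, all of whose libraries were on the same flow cell, 44 members were higher with shRASSF2-2 and 1 was not called (median 4.15, camera FDR 1.95e-29), and the call held with an estimated correlation (adjusted p = 0.0381). Without control replicate 1, and in the 7 libraries of the shared flow cell, 41 fell with shRASSF2-1 and 45 rose with shRASSF2-2; the control side of the 7 libraries is 1 library, whose own deviation counts as an effect.

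**Figure D3:**
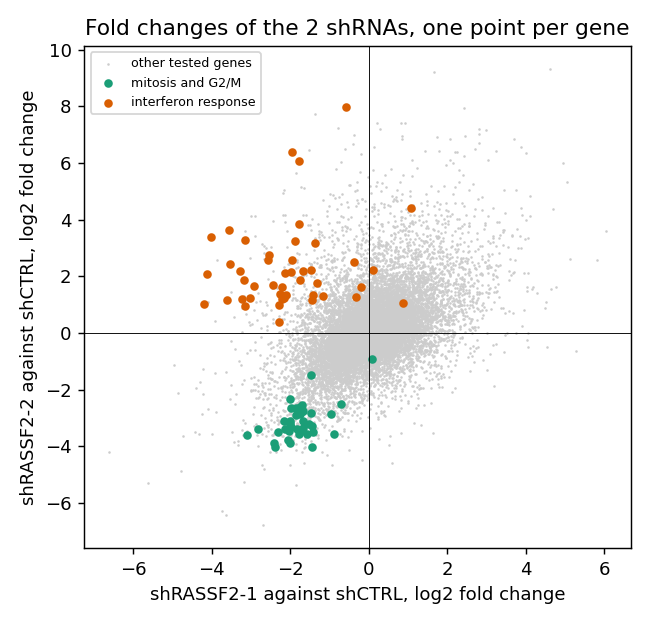
Log2 fold change against shCTRL with shRASSF2-1 (horizontal axis) and with shRASSF2-2 (vertical axis), 1 point per tested gene, with members of the mitosis and interferon response lists coloured. The mitosis genes lie at the lower left (medians -1.77 and -3.29) and most interferon response genes at the upper left (medians -2.14 and 1.88).

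**Figure D4:**
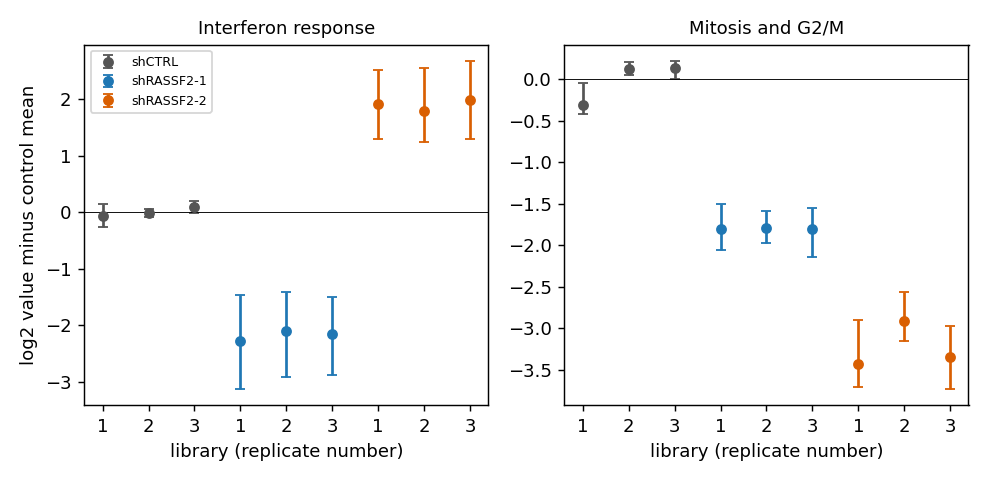
Log2 value minus the control mean (vertical axis) in each library (horizontal axis) for the interferon response and mitosis lists, where points are medians over the list's members and bars span the quartiles. Interferon response medians are -2.28 to -2.10 in the shRASSF2-1 libraries and 1.79 to 1.98 in the shRASSF2-2 libraries, and mitosis medians are -1.81 to -1.79 and -3.42 to -2.91.

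The 6 called genes highest with shRASSF2-2 relative to shRASSF2-1, at a mean of at least 5 CPM, were CXCL10, CXCL11, GBP1, SDS, ZBP1 and TNFSF18. The chemokine CXCL10 was at 65.8 ± 4.37 with shRASSF2-1 and 21972 ± 3060 with shRASSF2-2 (log2 difference 8.35), CXCL11 at 19.3 ± 6.86 and 4517 ± 705 (7.85), GBP1 at 15.9 ± 2.82 and 6280 ± 532 (8.55), and the serine dehydratase SDS at 15.2 ± 3.14 and 4047 ± 100 (7.99). ZBP1 was at 0.302 ± 0.524 and 693 ± 114, and the cytokine TNFSF18 was 0 in the shRASSF2-1 libraries and 264 ± 47.7 with shRASSF2-2. The 6 genes lowest with shRASSF2-2 relative to shRASSF2-1 were AKR1C2 (-5.91), TGM5 (-5.16), the neurotrophic factor gene ARTN (-4.57), AKR1C3 (-4.55), LOC101927851 (-4.45) and the anion exchanger SLC4A3 (-4.30). The largest limma adjusted p among these 12 genes was 2.65e-06, for ZBP1.

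Other lists also differed between the shRNAs. In shRASSF2-2 against shRASSF2-1, 26 of 34 Rac genes were higher and 4 lower (median 0.65, camera FDR 7.91e-06), and this call held with an estimated correlation (adjusted p = 0.0381). Actin nucleation genes had 20 higher and 3 lower of 27 (median 0.64, camera FDR 0.000235), and monocyte and macrophage genes 22 higher and 6 lower of 34 (median 1.31, camera FDR 0.000174), with adjusted p = 0.0717 and 0.128 with an estimated correlation. The mitosis list was lower with shRASSF2-2 than with shRASSF2-1 in 37 of 39 members (median -1.34, camera FDR 6.79e-12), and the DNA replication list in 34 of 41, with 1 higher (median -0.70, camera FDR 1.51e-06); with an estimated correlation the adjusted p was 0.316 for both. Counts adjusted over the list alone were equal for these 5 lists.

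Between the shRNAs limma called 9050 genes, 4647 higher and 4403 lower with shRASSF2-2, 4268 of them by at least 2-fold. With scaling by total reads the median of all genes moved from -0.03 to -0.41, and the split became 2905 higher and 7318 lower (51.3% and 28.4% higher). Of the genes called against control with both shRNAs, 1245 changed in opposite directions, 873 down with shRASSF2-1 and up with shRASSF2-2 and 372 the other way round. The count was 729 with flow cell as a covariate, 1355 in the 7 libraries of the shared flow cell, 754 in the edgeR test against a fold of 1.2 and 1764 without control replicate 1. Independent call lists would give 2644 such genes. Of the 4834 genes called in the same direction, 2532 also differed between the shRNAs. In the authors' deposited table, 13 of the 1245 genes had an adjusted p-value under 0.05.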

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

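The tests of the flow cell and of a monotonic response for the interferon genes, all tests of the tissue-type transcripts, the monotonic test and that of the flow cell as the whole cause for the cell division genes, and scaling by total reads were chosen only after the results were seen.

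Against control, 1245 genes changed in opposite directions with the 2 shRNAs (729 with flow cell as a covariate); a test between the shRNAs adds nothing for genes chosen that way. That test called the Rac GTPase signaling list (median 0.65 with shRASSF2-2 minus shRASSF2-1) and the interferon response list (median 4.15). For the 1245 genes and the Rac list no explanation was weighed separately.

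Interferon response genes were lower with shRASSF2-1 and higher with shRASSF2-2 than in the controls. A difference between flow cells is argued against for the gap between the shRNA groups. They shared a flow cell and still differed by a median of 4.15 (median SE 0.121), with 45 of 45 members higher with shRASSF2-2. That contrast holds no control library, so a part from the flow cell in either comparison with the controls stays open. Library scaling is argued against as well: with scaling by total reads the medians were -1.76 with shRASSF2-1 and 1.87 with shRASSF2-2 (median SE 0.122). A monotonic response to the RASSF2 mRNA level is argued against, since 0 of 45 members had the shRASSF2-2 mean between the other means, where RASSF2 itself lies. Effects of either hairpin on other targets, or of the transduced cultures, were not tested and stay open, as does a response to RASSF2 that is not monotonic.

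Some transcripts taken as markers of epithelium, connective tissue and vessel, FCGBP, SPARC, KRT18 and STAB1 among them, were near 0 in 2 control libraries. They were present in the 7 libraries of the other flow cell. Of 26 markers measured, 8 were higher in each of the 7 than in both others. Not all markers followed the flow cell. The liver markers APOB, FGA, FGB, FGG and AHSG had reads only in control replicate 3, shRASSF2-1 replicate 2 and shRASSF2-2 replicate 3. Normalized read counts of APOB were 41.2, 67.2 and 35.2 there, and 0 in all other libraries. Reads from other libraries of the shared flow cell cannot be told apart from other sources, expression by the cells themselves among them. The lowest summed level of the 7, 57.0 CPM, was 5.06 times the highest of the other 2, 11.3 CPM. But the sum holds the genes in which the pattern was seen. Without the 8 markers called up with both shRNAs it was 7.87 against 8.32 CPM. These are not the same 8 as those higher in each of the 7 libraries. HPX and COL6A3, which lack that pattern, were taken out, and KRT19 and AMBP, which show it, stayed in. A single source of fixed composition for all liver and gut epithelium marker reads is argued against. Their log2 ratio ranged over 2.99 in the 7 libraries, from -3.93 to -0.94. The ratio cannot decide on a single source beside expression by the cells themselves. Liver markers summed to 5.02 CPM in control replicate 1 and to 5.32 CPM in shRASSF2-1 replicate 1. Knockdown is argued against for control replicate 3 by the design, since it carried the control shRNA and had 79.6 CPM, or 7.07 times the higher of the other controls. That ratio restates the pattern, because the sum holds the genes in which it was seen. For the knockdown libraries an effect of knockdown cannot be told apart from the flow cell. There 1 of 6 lay below control replicate 3, and that flow cell held only 1 control.

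The DNA replication and mitosis lists, 80 genes together, were lower with both shRNAs. Their calls at the preset correlation were lost with an estimated correlation. There the camera adjusted p was 0.139 and 0.0726 for DNA replication, and 0.243 and 0.141 for mitosis. Library scaling is argued against, since with scaling by total reads the medians were -1.38 with shRASSF2-1 and -2.86 with shRASSF2-2 (median SE 0.166). A monotonic response to the RASSF2 mRNA level is argued against as well, within these libraries only. Of 80 members, 6 had the shRASSF2-2 mean between the other means, and 74 were lower with shRASSF2-2, the shRNA that left more RASSF2 mRNA. Members that vary together are not 80 separate tests. With an estimated correlation the difference between the shRNAs was not called for either list (camera adjusted p = 0.316 for both). With flow cell as a covariate the medians were -1.79 with shRASSF2-1 and -2.97 with shRASSF2-2 (-1.75 and -2.84 without it). Both lists kept their calls at the preset correlation. With shRASSF2-1 the covariate moved the log2 fold change of 395 other genes by over 1 and of 0 members. The median lay -8.03 median SEs from 0 with shRASSF2-1 and -13.4 with shRASSF2-2, which argues against the flow cell as the whole cause, but the control side rests on 1 library, so a part from the flow cell stays open beside loss of RASSF2, which the design names.

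Other splits of the libraries were compared with the real groups. For shRASSF2-1 against control, shRASSF2-2 against control and shRASSF2-2 against shRASSF2-1, 1 of 10 splits gave as many genes, the real one with 8669, 9417 and 9050, and the highest other split gave 0 each time. Those splits are too few for a share under 0.05. For genes called in the same direction with both shRNAs, 1 of 100 splits drawn from 840 gave as many, the real one with 4834. The highest other gave 3563. Every other drawn split mixed libraries of different groups, which widens the spread within groups. The comparison therefore does not exclude a random arrangement of the libraries for that count. None of the drawn splits exchanged whole groups. Such exchanges gave 4088 genes with shRASSF2-1 in the control role, fewer than the real 4834. With shRASSF2-2 in that role they gave 5583, more than the real count. The count therefore does not show that the control is the group apart.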

How the results depend on the processing

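Scaling by total reads, the edgeR test with TMM and the list tests on 7 libraries were chosen after the data were seen. Under every alternative run, the total counts of genes called in the 4 comparisons stayed within 1.5 times the values reported. Counts by direction did not: genes in opposite directions went from 1245 to 729 with flow cell as a covariate and to 754 in the test against a fold of 1.2, those up with both from 2248 to 1447 with the covariate, and scaling by total reads moved those with shRASSF2-1 from 4160 up and 4509 down to 6981 and 2596 and those lower with shRASSF2-2 than shRASSF2-1 from 4403 to 7318. RASSF2 stayed called with log2 fold changes of -2.86 to -2.33 with shRASSF2-1 and -1.85 to -1.66 with shRASSF2-2. Leaving out each library gave 7434 to 10231 genes with shRASSF2-1, 8392 to 10710 with shRASSF2-2, 4175 to 5930 with both and 7888 to 10986 between the shRNAs. With flow cell as a covariate the counts were 6420, 7484, 3453 and 9343. The list test called 13 lists with shRASSF2-1 and 18 with shRASSF2-2 at the preset correlation, and 0 and 0 with an estimated correlation, which allows for members that vary together. Scaling by total reads turned 3 named genes with shRASSF2-1, ASAP1 (0.0174), ERAP1 (0.0646) and CD4 (0.0167), by a shift of the median of all genes from 0.02 to 0.39. KRT18 with shRASSF2-1 turned to -0.45 with flow cell as a covariate and to -0.45 in the 7 libraries of the shared flow cell; the cause was not tested beyond the marker levels above. Over the other gene values and alternatives 7205 stayed the same, 102 became weaker, 22 stronger and 14 moved; for lists 1252 stayed the same, 64 became weaker, 13 stronger and 15 moved. Replicate numbers are shared by the groups without a stated pairing: same-number libraries had deviations correlated at -0.16 to 0.12, and 0 libraries correlated best with their own number in both other groups. The replicate block gave 8289, 9126, 4574 and 8754 genes, and 13 and 17 lists, with the Rac list at camera FDR 0.0558 for shRASSF2-2.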

Other observations

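Genes in this paragraph were chosen after their values were seen. No list or test stands behind the groupings made here. CD163 does belong to the monocyte and macrophage list, and DDX58 and IFIH1 to the interferon response list. With shRASSF2-2, these genes of iron and antioxidant metabolism rose: HMOX1, which degrades heme, from 335 ± 90.7 to 40710 ± 3858 (log2 fold change 6.95, limma adjusted p = 1.81e-09; 0.86 with shRASSF2-1), the ferritin chains FTH1 (3.61; 1.10 with shRASSF2-1) and FTL (2.46), and GCLC, of glutathione synthesis (3.18). NQO1 rose by 1.93 while TXNRD1 fell by 0.77. Other genes that rose with shRASSF2-2 were GPNMB (6.04), the fatty acid binding protein FABP4 (5.23), the transcription factor MAF (5.34), the hemoglobin receptor CD163 (6.71) and the lysosomal protease CTSD (3.78). LPL, lipoprotein lipase, had -2.89 with shRASSF2-1 and 3.45 with shRASSF2-2, and FABP5 -1.65 and 1.68. The RNA sensors DDX58 (-1.67 and 2.20) and IFIH1 (-1.46 and 2.22), already counted in the interferon response list, fell with shRASSF2-1 and rose with shRASSF2-2. The metallothioneins MT1F (-2.60 and -1.07) and MT1X (-3.26 and -1.11) fell with both, and near-identical copies leave them uncertain.

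A window of 5 neighbouring genes at 1p34.2 (chromosome 1, 40040240 to 40317286) had the highest median level of 15181 windows, 1912 CPM, against 594 CPM in the next separate window. It holds CAP1 (9496 CPM, rank 1 of 15277 genes), PPT1 (3224 CPM), RLF (669 CPM), ZMPSTE24 (1353 CPM) and COL9A2 (1912 CPM). In 1000 shuffled gene orders the highest window reached 1260 CPM, a share of 0.001, the smallest these shuffles can give, so chance placement is argued against. A candidate explanation is a local gain in copy number in this line, which was not tested. CAP1 (log2 fold changes -1.58 and 0.69), PPT1 (-0.75 and 0.60) and RLF (-0.45 and 0.33) fell with shRASSF2-1 and rose with shRASSF2-2, COL9A2 rose with both, and ZMPSTE24 was not called with either. CAP1 and PPT1 overlap by position, and with the strand not stated their levels are uncertain.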
